A study of Mus musculus with 103 samples.

How the data were processed

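Single-cell transcriptomes of sorted mouse mammary epithelial cells were analysed from deposited values. Per the labels' protocols, cells were captured on a Fluidigm C1 chip, cDNA was made with the SMARTer Ultra Low RNA kit without spike-in RNA, equal amounts of cDNA per cell were made into Nextera XT libraries with 96 indices, and these were sequenced as paired ends. SMARTer chemistry copies full-length transcripts and adds no molecular identifiers, so fragments include PCR copies and intervals cover counting error only. Per the submitters' processing notes, Bowtie2 2.2.3, RSEM and the mouse build mm10 were used. Their settings and the RSEM version are not given in usable form in the sources used here. The authors deposited FPKM per gene, that is, fragments scaled to transcript length and to the mapped fragments of the cell, for each cell. RSEM splits fragments shared between genes by an estimate, so genes with near-identical copies, such as ribosomal proteins, mitochondrial genes with nuclear copies, Hspa1a and Hspa1b, or class I genes, are uncertain. The authors' normalization leaves each gene relative to the whole of its cell, and the FPKM of a cell summed to between 688822 and 2184290.

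Each file listed 46517 genes, of which 16644 were above 0 in at least 1 cell and 29873 were listed at 0 in all. Gene identifiers were matched to GENCODE mouse release M21, on the same build as mm10 (46005 of 46517 found; the authors' annotation is not given in the sources used here), for coordinates and biotypes. For the 83 symbols with more than 1 identifier, the copy with the highest mean was used. Depth was recovered from the FPKM steps: in 2938 coding genes with 1 annotated transcript over 1000 bases, FPKM times the length less 200 bases gathers around the worth of 1 fragment, and the densest window of 0.08 on the log10 scale gave the number of fragments. In simulated libraries the estimate was 0.998 to 1.01 times the truth in 20 draws. These were drawn with the same genes, lengths and 200-base offset, so they check the calculation and not the authors' annotation or RSEM's split of fragments. In the real libraries the window held at least 12 genes, and a median of 30.8% of the detected genes with 1 transcript.

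The design choices in this paragraph were fixed before the data were examined, other than that on names for small clusters. Cells entered with at least 1000 genes at 1 FPKM or more, which kept 93 and left out 10. Values were used as log2(FPKM + 1), so differences understate the change of low genes. The 7895 genes at 1 FPKM or more in at least 5 kept cells were divided by a hash of their identifier into a clustering set (3877 genes without the lists) and a held-out set (3870). The 1000 genes of the clustering set with the highest variance over the trend with the mean were scaled, reduced to 10 principal components and clustered by Ward linkage, with the number of clusters from 3 to 8 of the highest silhouette width (7, at 0.217). Clusters were compared only on 32 fixed gene lists and on the held-out set. A list member counted as higher where the ratio of (mean FPKM + 1) was at least 2, the share of cells at 1 FPKM lay on the same side, and that share was at least 20%. List medians are given with their percentile among 10000 random lists of held-out genes matched on mean expression, which describes these cells and tests nothing. Named genes were list members, those with the largest ratios before others, and for each cluster the 10 held-out genes with the largest ratio to any other cluster, with a mean of at least 10 FPKM and 1 FPKM or more in at least 50% of its cells. Clusters were named only where at least 3 fixed markers of a type led, and clusters of 10 cells or fewer in the kept cells were left unnamed after the data were seen. No doublet caller was run on so few cells, and keratins found together were counted instead. No test across samples was possible with 1 sample.

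A further clustering was set up after the data were seen, because 26 of the kept cells lay under 100000 fragments and small clusters followed plate rows and columns. It took the 67 cells with at least 100000 fragments, genes at 100 FPKM or more in at least 5 cells (1037 in the clustering set), log2(FPKM + 100) and 3 clusters. The silhouette rule would have given 7 clusters there (0.226, against 0.216 at 3), which divide the basal-like cells and leave the clusters of 19 and 8 cells as they are. The depth limit, the pseudocount of 100, the level of 100 FPKM, the number of clusters, the name by the list with most leading markers where more than 1 list met the count, the size rule with shares at 100 FPKM, and a filter that sets to 0 values under 1% of the highest fragment weight in the plate row or column were all chosen after the data were seen. Plate rows and columns come from the well in each sample's label. The wells lie in 9 rows of up to 12, more wells than the 96 indices, and the labels do not say how row I, with 7 cells, was run.

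The clustering was tested on simulated data made from real values shuffled per gene. With 3 planted groups whose genes differed in detection, both clusterings recovered the groups (adjusted Rand index 1.00), that of the deeper cells with the number of clusters given, since the silhouette rule chose more clusters than were planted. An earlier scheme with 8-fold changes and no change in detection was recovered in the deeper cells (1.00) and poorly in the kept cells (0.207), and the scheme was changed after that result was seen. Both schemes planted groups of near equal size and changed a large share of the deeper cells' clustering set. The clusters found in the deeper cells held 40, 19 and 8 cells, so recovery of a group as small as 8 was not tested. With no groups, silhouette widths reached 0.0665 and 0.0789. Shuffling each gene also removes differences in depth and plate position between cells, so these widths do not show what either alone would give. Of lists without a shift 3.5% lay above the 95th percentile, and of lists shifted by a log2 of 3, 89% did.

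The alternatives tried were other pseudocounts, gene filters, numbers of variable genes, components and clusters, the held-out set in place of the clustering set, all genes with the lists, Leiden clustering, rescaled FPKM, other cell filters, other detection levels, leaving out rows and leaving out each gene's highest cell. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0, statsmodels 0.14.6 and leidenalg 0.10.2, and figures matplotlib 3.10.9. The result of 1 gene is not reported.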

Results

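Epithelial cells sorted from the mammary gland of 8-week-old C57BL/B6 mice were captured on a Fluidigm C1 chip, a microfluidic device that isolates single cells in separate chambers, and sequenced as single-cell libraries, 1 per cell. The labels give 1 untreated group and name no animal, so the cells count as 1 biological sample. No p-value is given below. SDs describe the spread among cells, exact Clopper-Pearson 95% intervals cover counting error only, and no difference has a replicate check. The question addressed was which cell classes the sort held and which genes set them apart.

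The authors' values are FPKM per gene and cell. The fragments behind each library, recovered from the FPKM worth of 1 fragment, ranged from 425 to 6503650 with a median of 651865. Libraries fell on both sides of a gap: 36 held at most 60181 fragments and 67 held at least 198785, with a median of 2943080. A total of 93 cells (90.3%) had at least 1000 genes at 1 FPKM or more and were kept, with 1027 to 3395 genes and a median of 2137. The 10 cells left out had 308 to 770 genes and included all 9 wells of plate column 5. Of the 93 kept cells, 26 lay under 100000 fragments. Mitochondrial genes took a median of 10.6% of the FPKM of kept cells, with a range of 1.78% to 77.9%.

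**Figure D1:**
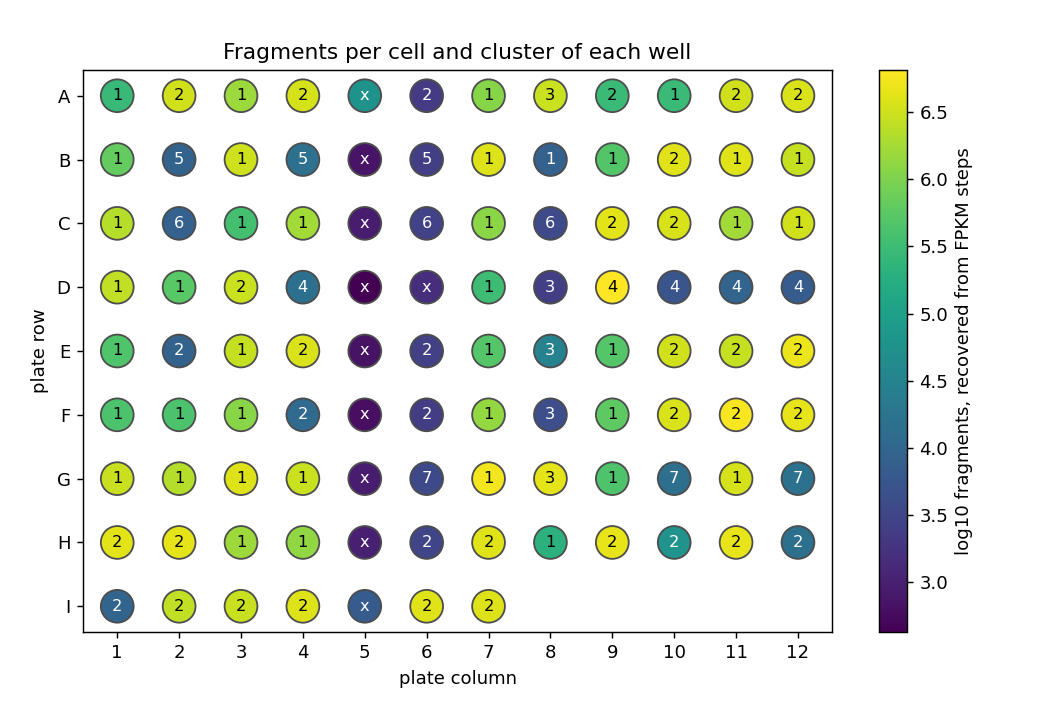
Each circle is 1 well at its plate row and column, colored by the log10 number of fragments and marked with its cluster among the 93 kept cells (x, left out). Column 5 was left out as a whole, and clusters 3 to 7 each lay in 1 row or 1 column.

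Krt14 was found in nearly every kept cell, and Krt5, Krt8 and Krt18 in fewer. Krt14, the type I keratin of basal and myoepithelial cells (ENSMUSG00000045545, chromosome 11, 100203162 to 100207548, minus strand, mm10), was at 1 FPKM or more in 92 of 93 kept cells, with a mean of 1163 FPKM ± 1348 (SD, n = 93 cells). Its partner Krt5 (ENSMUSG00000061527, chromosome 15, 101707070 to 101712898, minus strand) was at 1 FPKM or more in 37 of 93 cells (39.8%, interval 29.8% to 50.5%). Among luminal keratins, Krt8 (ENSMUSG00000049382, chromosome 15, 101996698 to 102004482, minus strand) reached that level in 48 cells (51.6%, 41.01% to 62.1%) and Krt18 (ENSMUSG00000023043, chromosome 15, 102028180 to 102032027, plus strand) in 64 cells (68.8%, 58.4% to 78.02%). Epcam, the epithelial adhesion molecule (ENSMUSG00000045394, chromosome 17, 87635979 to 87651129, plus strand), reached it in 67 cells (72.04%, 61.8% to 80.9%).

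These shares depended on the level asked for. In the 67 cells with at least 100000 fragments and at 100 FPKM or more, Krt14 was found in 43 cells (64.2%, 51.5% to 75.5%), Krt18 in 16 (23.9%, 14.3% to 35.9%), Epcam in 11 (16.4%, 8.49% to 27.5%), Krt8 in 9 (13.4%, 6.33% to 23.97%) and Krt5 in 8 (11.9%, 5.30% to 22.2%). In 8 endothelial-like cells described below, which should lack these genes, Krt14 was at 1 FPKM or more in 8 of 8, and Krt18 and Epcam in 6 of 8 each, while Krt5 and Krt8 reached that level in 0 of 8. Their median depth was 1552350 fragments, against 3764300 in the basal-like cells. None of the 5 genes reached 100 FPKM in any of these 8 cells. The shares of Krt14, Krt18 and Epcam at 1 FPKM therefore lie at the background of these libraries, and the planned levels of 1 and 10 FPKM are kept below with some counts at 100 FPKM, a level chosen after the data were seen, beside them.

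Blood and stromal markers ranged from lists at 0 throughout to lists found in part. Ptprc, the pan-leukocyte phosphatase CD45, was at 1 FPKM or more in 0 of 93 kept cells, of which 26 lay under 100000 fragments, and in 0 of the 67 deeper cells. The latter allows a share of up to 4.48% (3 counts of 67; the exact 95% limit is 5.36%) of cells with Ptprc at that level, which does not limit the share that expresses it. All 5 erythroid genes found in the files, among them Hba-a1 and Hbb-bs, were listed at 0 in all cells. Of 8 macrophage markers 6 were listed at 0 in all cells (Adgre1, Lyz2, Aif1, C1qa, C1qb and Fcgr3), as were 6 of 10 lymphocyte markers, 4 of 6 antigen presentation markers including Cd74, and 4 of 5 adipocyte markers including Adipoq. Listed at 0 were also 2 of 5 pan-immune markers, 2 of 7 pericyte markers, 1 of 4 Schwann cell markers and 0 of 8 endothelial markers. Rgs5, a pericyte marker, was at 1 FPKM or more in 16 of 93 cells and at 100 FPKM or more in 2 of 67. Of 8 fibroblast markers, 6 were listed at 0, including Col1a2, Col3a1 and Pdgfra. Dcn, a matrix proteoglycan and 1 of the members found, averaged 173 FPKM ± 525 (n = 40) in the basal-like cells, with 7 cells at 100 FPKM or more and a mean of 101.2 without the highest. The housekeeping genes were all found, with each of the 8 at 100 FPKM or more in at least 20% of the 67 deeper cells.

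Luminal differentiation genes were sparse. Of 9 hormone-sensing markers, 4 were listed at 0 in all cells: Foxa1, a pioneer factor of estrogen receptor target genes, Areg, Cited1 and Tnfsf11. Of 10 luminal progenitor markers, Cd14, Ltf and Lalba were listed at 0, and Lcn2 alone was at 100 FPKM or more in at least 20% of the deeper cells. The milk protein genes Csn2, Wap, Lalba, Glycam1, Csn1s2a and Btn1a1 were listed at 0 in all cells. Mki67 and Top2a, markers of cycling cells, were each at 1 FPKM or more in 1 of 93 cells (1.08%, 0.0272% to 5.85%). Of 15 cell cycle genes, 2 (Cdk1 and Ccna2) were listed at 0 in all cells. Pcna, a DNA replication clamp also used in repair, was at 100 FPKM or more in 23 of 67 deeper cells (34.3%, 23.2% to 46.9%), and Tyms was at 1 FPKM or more in 39 of 93 cells and at 100 FPKM or more in 1 of 67.

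Basal and luminal keratins were found together in many cells. Krt5 or Krt14 and Krt8 or Krt18 both reached 10 FPKM in 52 of 93 kept cells (55.9%, 45.2% to 66.2%), basal keratins alone in 36 (38.7%, 28.8% to 49.4%), luminal keratins alone in 1 cell (1.08%) and neither in 4. For Krt14 that level lies within the background, since 5 of the 8 endothelial-like cells held basal keratins alone at 10 FPKM and their Krt14 reached 41.6 FPKM, while 0 of 8 held luminal keratins at that level. The 93 cells also include the 26 under 100000 fragments, and with values under 1% of the highest in the plate row or column set to 0 the share was 31.2%. That filter compares FPKM times fragments, so it takes more values from shallower wells, and the lower share may in part follow depth. At 100 FPKM in the 67 deeper cells, 19 (28.4%, 18.01% to 40.7%) held both, 24 (35.8%, 24.5% to 48.5%) basal keratins alone and 1 luminal keratins alone. All 19 belonged to the basal-like cluster. No doublet caller was run on so few cells, so such cells stay undivided between doubly positive cells and 2 cells in 1 capture site.

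Clustering of the 93 kept cells on 1 of 2 random gene sets, without the marker lists, set apart 2 large groups that differed in basal and endothelial genes. Cluster 1 held 39 cells (41.9%, 31.8% to 52.6%) at a median of 1317180 fragments, and cluster 2 held 35 (37.6%, 27.8% to 48.3%) at 3512720. Of the cell classes described below, cluster 1 mixed 11 basal-like, 8 endothelial-like and 19 high mitochondrial cells, and cluster 2 held 26 basal-like cells. Cnn1, a calponin of the contractile apparatus, averaged 266 FPKM ± 441 (n = 35) in cluster 2 and 19.5 ± 63.1 (n = 39) in cluster 1. Col17a1, a collagen of hemidesmosomes, averaged 80.4 ± 168 and 7.59 ± 25.6. Without the highest cell of cluster 1 the means there were 9.99 (Cnn1) and 3.95 (Col17a1). Conversely, Esam, an adhesion molecule of endothelial junctions, averaged 209 ± 694 in cluster 1 and 5.94 ± 28.7 in cluster 2, and 130 and 1.14 without each cluster's highest cell.

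By the size rule fixed before the data were examined, 5 of 11 basal markers were higher in cluster 2 (Krt5, Mylk, Cnn1, Trp63 and Col17a1) and none was lower, and with shares at 100 FPKM 9 were higher. The median log2 difference of the list was 2.17, at percentile 99.7 of random lists matched on mean expression. The contractile list had 6 of 12 members higher (8 at 100 FPKM) and a median of 1.64 (percentile 99.5), and 5 of its members are also basal markers. Tpm1 averaged 645 FPKM ± 645 in cluster 2 and 163 ± 397 in cluster 1. Of 15 stem cell associated genes 7 were higher (5 at 100 FPKM, median 1.5, percentile 98.7), among them Cd24a at 274 ± 394 and 23.8 ± 79.7 (14.6 without the highest cell), and Lgr5, a Wnt pathway receptor, at 85.2 ± 157 and 18.97 ± 94.4. Without the highest cell, the Lgr5 mean in cluster 1 was 3.96. Of 9 shared luminal markers, Krt18 and Gata3 were higher in cluster 2 (median 1.09, percentile 88.5).

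All 8 endothelial markers were lower in cluster 2, with a median log2 difference of -2.87 (percentile 0.03). With shares at 100 FPKM the size rule counted 0 of the 8, and a few cells carried the difference: Esam was at 100 FPKM or more in 4 of 39 cells of cluster 1 and had a median of 0.53 there. Egfl7 averaged 490 FPKM ± 1673 in cluster 1 (283 without the highest cell) and 173 ± 715 in cluster 2, the latter 57.8 without the highest cell, and Cldn5, a tight junction protein of endothelium, 206 ± 722 and 13.5 ± 41.2. Without each cluster's highest cell the Cldn5 means were 104 and 7.83. Of 6 class I antigen presentation genes, H2-K1 met the size rule as lower in cluster 2 through 1 cell, and 5 met it in neither direction (list median -0.71, percentile 1.69, and -0.16 without each gene's highest cell). H2-K1 averaged 1029 FPKM ± 3169 in cluster 1 and 503 ± 706 in cluster 2, and 569 and 452 without the highest cells, while its medians were 24.2 and 80.3. Among 12 mesenchymal genes Vim was lower, at 75.2 ± 179 against 160 ± 437, and the median was -0.29 (percentile 0.53). The sign of that median turned to 0.16 when all cells were clustered.

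Cluster 1 had a median mitochondrial share of 17.4% and cluster 2 of 8.84%. Neither earned a cell type name, since fewer than 3 markers of any list led in either. Clusters 3 to 7 held 5, 5, 3, 3 and 3 cells, each within 1 plate row or column, and 16 of these 19 cells lay under 100000 fragments. Cluster 6 met the count for a name with 3 leading endothelial markers (Pecam1, Tek and Esam), but clusters this small were left unnamed. With 2000 variable genes, 1 cluster of 62 cells held 35 of the 39 cells of cluster 1 and 22 of the 35 of cluster 2. The genes that led the held-out gene set often rested on 1 cell: Id3 averaged 15263 FPKM in cluster 1 and 829 without its highest cell, and Smarca5 2558 in cluster 2 and 176 without it.

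Among the 67 cells with at least 100000 fragments, clustered in a way chosen after the data were seen, 40 were basal-like (59.7%, 47% to 71.5%) and 8 were endothelial-like (11.9%, 5.30% to 22.2%). A cluster of 19 cells (28.4%, 18.01% to 40.7%) with a high median mitochondrial share stayed unnamed. Of the 8, 7 held at least 1 endothelial marker at 100 FPKM or more and 5 held at least 2. Basal-like cells carried Krt14 at a mean of 1825 FPKM ± 1600 (n = 40), against 15.4 ± 13.02 (n = 8) in the endothelial-like cells and 146 ± 218 (n = 19) in the unnamed cluster. Tagln, an actin-binding protein of contractile cells, averaged 1817 ± 2108, 10.98 ± 8.69 and 54.7 ± 99.1 in the same order. In the endothelial-like cells Emcn, a sialomucin of vascular endothelium, averaged 623 ± 1080, against 6.81 ± 23.6 in the basal-like cells; without its highest cell the former mean was 364. Gpihbp1, which carries lipoprotein lipase across capillary endothelium and took no part in the clustering, was at 100 FPKM or more in 8 of 8 endothelial-like cells, with a mean of 4040 ± 3925 and 3094 without the highest cell.

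**Figure D2:**
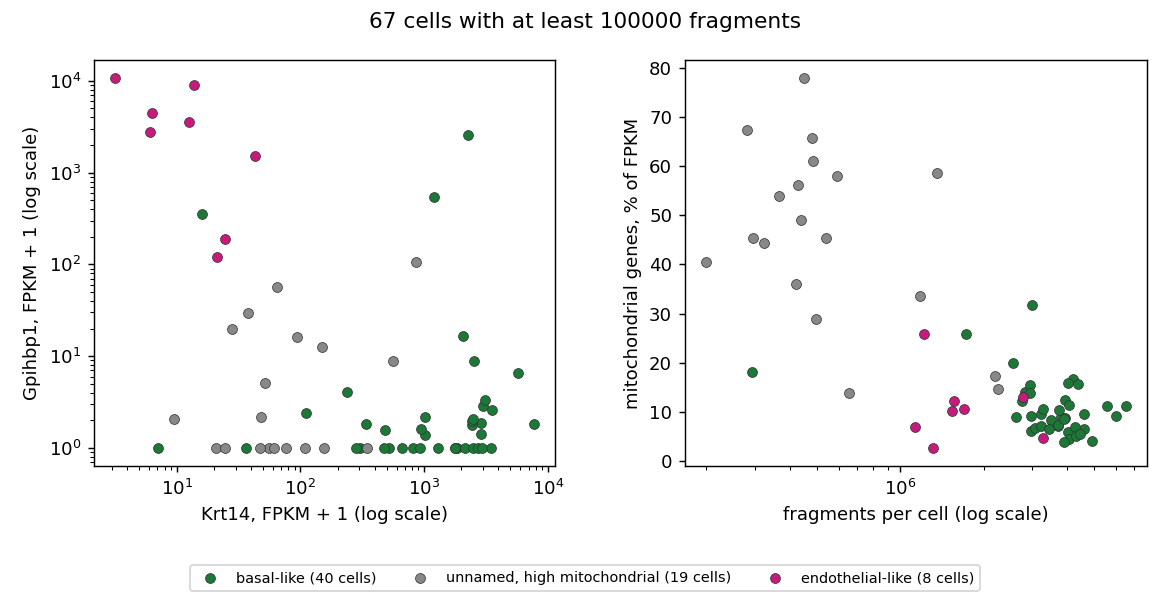
Each point is 1 of the 67 cells with at least 100000 fragments, colored by cluster. The left panel plots Krt14 against Gpihbp1 (FPKM + 1, log scales), and the right panel plots fragments per cell (log scale) against the mitochondrial share of FPKM. The 8 endothelial-like cells all lay under 100 FPKM of Krt14, and the unnamed cluster had a median mitochondrial share of 45.3%.

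Basal-like cells exceeded endothelial-like cells in most basal and contractile markers. Of 11 basal markers 9 led in the basal-like cells. Of 9 shared luminal markers 3 led there too (Krt8, Krt18 and Gata3), which also meets the count for a name, and the list with more leading markers gave the name. The median log2 difference of the basal list was 6.17 (percentile 100 of matched random lists). The size rule counted 6 of the 11, since it asks for a higher share of cells at 1 FPKM and Krt14 and Krt17 were at that level in all cells of both clusters. With the share taken at 100 FPKM it counted 9. Krt17 averaged 1601 FPKM ± 1549 and 21.2 ± 18.2. Acta2, smooth muscle actin (ENSMUSG00000035783, chromosome 19, 34241090 to 34255590, minus strand), averaged 966 ± 1398 and 6.74 ± 3.80. Trp63, a basal cell transcription factor, averaged 71.5 ± 184 and 0.210 ± 0.183. The contractile list had 6 of 12 members higher (9 at 100 FPKM) and a median of 5.52. Myh11, smooth muscle myosin, averaged 87.1 ± 107 and 0.843 ± 0.436.

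Some luminal and epithelial genes were also higher in the basal-like cells. Krt18 averaged 283 FPKM ± 526 there and 1.47 ± 1.11 in the endothelial-like cells, and Gata3, a regulator of luminal fate, 87.5 ± 108 and 0.621 ± 0.616, with 16 of 40 and 0 of 8 cells at 100 FPKM or more for each. Of 9 shared luminal markers 2 were higher by the size rule, Krt8 and Gata3 (3 at 100 FPKM), and the list median was 3.77 (2.59 without each gene's highest cell). Of 5 shared epithelial markers 2 were higher (median 5.07, percentile 95.2), while 0 of 9 hormone-sensing markers (median 1.67, percentile 68.1) and 0 of 10 luminal progenitor markers (1 at 100 FPKM, median 0.00899, percentile 25.6) met the rule. For the 11 keratins the median was 4.93, with 3 higher (5 at 100 FPKM). Lcn2, a luminal progenitor marker and secreted iron-sequestering protein, averaged 1782 ± 2223 in basal-like and 17.6 ± 14.3 in endothelial-like cells.

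Of 15 stem cell associated genes 6 were higher in basal-like cells (4 at 100 FPKM, median 3.61), including Lgr5 at 95.8 FPKM ± 175 against 0.899 ± 0.745 and Sox9 at 101.4 ± 155 against 2.26 ± 2.42. Itga6 went the other way through a single cell: it averaged 649 ± 1830 in the endothelial-like cells and 2.25 without the highest, against 138 ± 208 in the basal-like cells. The Wnt list had 5 of 15 members higher (2 at 100 FPKM), 1 lower and a median of 3.64, with Lgr4, a receptor for R-spondins, at 219 ± 225 and 6.51 ± 6.70. The Notch list had 3 of 11 members higher (1 at 100 FPKM), 1 lower and a median of 0.42 (percentile 16.9). Its member Jag1, a Notch ligand, averaged 242 ± 225 and 43.4 ± 110, the latter 4.56 without its highest cell.

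Endothelial markers and 3 of 6 class I antigen presentation genes were higher in the endothelial-like cells. All 8 endothelial markers were lower in the basal-like cells (median -4.46), and 7 of the 8 led in the endothelial-like cells. Egfl7 averaged 1765 FPKM ± 3106 (824 without the highest cell) against 103.2 ± 644, of which 1.36 remained without the highest basal-like cell. Pecam1, an adhesion receptor of endothelial junctions (ENSMUSG00000020717, chromosome 11, 106654217 to 106750628, minus strand), averaged 191 ± 355 (77.9 without the highest cell) against 5.77 ± 33.2, of which 0.530 remained without the highest cell. B2m, the light chain of class I molecules, averaged 7948 ± 3508 and was at 100 FPKM or more in 8 of 8 cells, against 990 ± 1342 in the basal-like cells. H2-D1 averaged 1876 ± 1454 and 431 ± 677. Of 6 class I genes 3 were higher in the endothelial-like cells by the size rule (H2-K1, H2-D1 and Tapbp; 4 at 100 FPKM), with a list median of -2.17 for basal-like minus endothelial-like, which was -0.93 without each gene's highest cell.

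**Figure D3:**
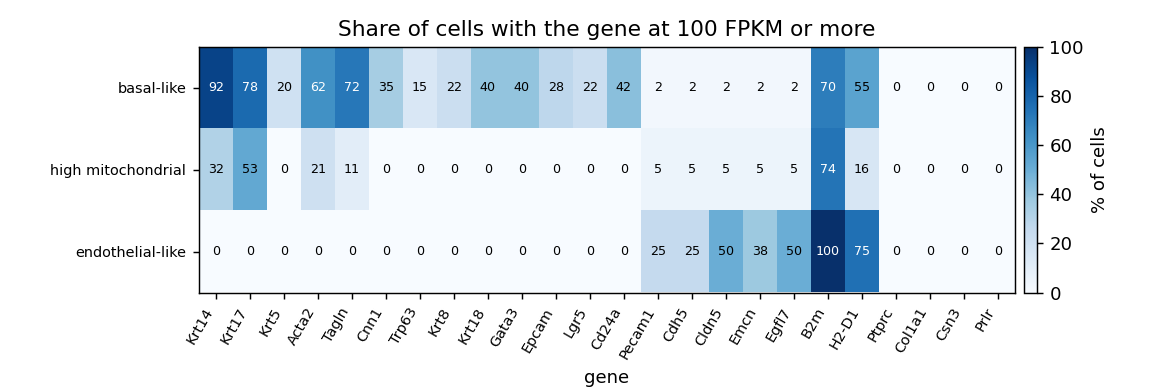
Percent of cells with each gene at 100 FPKM or more, by cluster of the 67 deeper cells (40 basal-like, 19 high mitochondrial, 8 endothelial-like). Krt14 reached that level in 92.5% of basal-like and 0 of 8 endothelial-like cells, and B2m in 100% of endothelial-like cells.

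Other held-out genes that led in the endothelial-like cells were Adgrf5, an adhesion receptor of endothelium, at 256 FPKM ± 417 and at 100 FPKM or more in 37.5% of the cells, and Mcf2l at 413 ± 838. Without the highest cell their means were 124 and 122. Ces1d and Itch fell from 580 and 86.7 to 1.28 and 4.86 without 1 cell. In the basal-like cells the held-out leaders were Rnase4 at 222 ± 487, Tmem258 at 149 ± 240 and Pttg1ip at 327 ± 1164, the last 149 without its highest cell. Trp53 averaged 462 ± 784 there and at most 7.21 in either other cluster.

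The 19 cells of the unnamed cluster had a median of 481491 fragments, 0.164 times that of all 67 cells, and a median mitochondrial share of 45.3% against 9.13% in the basal-like and 10.4% in the endothelial-like cells. The ranges overlapped, at 13.8% to 77.9% in the unnamed, 3.94% to 31.8% in the basal-like and 2.67% to 25.8% in the endothelial-like cells. Many lists lay lower than in basal-like cells, with median log2 differences, basal-like minus unnamed, of 4.69 (basal, percentile 99.3), 3.99 (stem cell associated, 99.3), 3.75 (keratins, 99.8), 3.40 (shared luminal, 98.1) and 1.81 (housekeeping, 66.2). The basement membrane and adhesion list had a median of 2.31 at percentile 37.9, so matched random lists lay lower in the unnamed cells as well. Of 11 basal markers the size rule counted 4, and 9 with shares at 100 FPKM. Endothelial markers went the other way, with 6 of 8 higher in the unnamed cells (0 at 100 FPKM) and a median of -1.68 (percentile 0.24), or -0.95 without each gene's highest cell. In the sex-linked list 2 of 5 were higher in the unnamed cells (Xist and Uty), with a median of -2.10 (percentile 0.76). That list mixes X-linked Xist with Y-linked genes, so its median has no single meaning. Uty reached at most 43.7 FPKM in the unnamed cells, and Ddx3y and Eif2s3y were listed at 0 in all cells. Xist rested on 1 cell, at a mean of 148 FPKM ± 626 and 4.19 without it. At least 1 endothelial marker was at 100 FPKM or more in 6 of the 19 cells. Krt14 was at 100 FPKM or more in 6 of 19 cells and Krt17 in 10. Tpm1 averaged 11.8 FPKM ± 10.9 against 598 ± 673, and Rplp0, a ribosomal protein gene, 114 ± 224 (64.3 without the highest cell) against 1477 ± 1357. A single cell set the level of Cldn5 in this cluster, which averaged 218 ± 937 and 3.25 without the highest cell. Gm28437, a nuclear copy on chromosome 1 whose 31-base words all occur in mitochondrial genes, averaged 168069 ± 134073, so its value holds mitochondrial reads. The mitochondrial shares given here count only genes annotated as mitochondrial and leave such copies out.

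Transcripts also appeared across wells along the rows and columns of the plate. For 282 genes with at least 95% of their fragment weight in 1 of the 67 deeper wells, other deeper wells of the same row were above 0 FPKM in 64.97% of gene and well pairs (1261 of 1941), wells of the same column in 55.9% (915 of 1636) and the remaining deeper wells in 3.91% (588 of 15035). In the 36 shallower wells the percentages were 42.5, 55.03 and 0.327. Where above 0 in deeper wells, the level was a median of 0.0397% of the source in the row, 0.0281% in the column and 0.0404% elsewhere. With pairs at 0 included the medians were 0.0226%, 0.0110% and 0%. Pairs of the same column were above 0 in 46.01% with 1 well in row I (75 of 163) and in 57.03% without (840 of 1473), and the remaining pairs with a well in row I in 3.90%. Tox2, a transcription factor gene found at 116800 FPKM in well H10, was above 0 in 10 of 11 other wells of row H, 6 of 7 other wells of column 10 and 1 of 84 remaining wells. Tox2 was chosen after its values were seen.

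**Figure D4:**
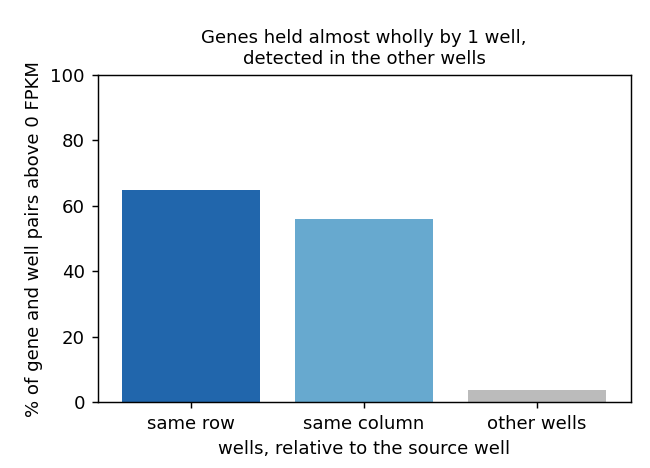
Percent of gene and well pairs above 0 FPKM for 282 genes held almost wholly by 1 well, by the place of the other well among the 67 deeper wells. The bars stand at 64.97% for the same plate row, 55.9% for the same column and 3.91% for the remaining wells.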

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

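All tests in this part were chosen after the results were seen. The 10 cells left out for low gene numbers had a median of 908 fragments. Of these 10, 7 held Krt14 at 1 FPKM or more (70%) and were singled out because a count of 0 would allow 30%. Krt14 at that level was also found in 8 of 8 endothelial-like cells, so the count does not tell RNA of these wells from background. In 1 of the 10, well I5 with 6708 fragments, a single gene, Ndufa12, took 82.1% of the FPKM, singled out as the highest value among them.

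Small clusters followed the plate: 5 clusters with 19 cells in all each lay in 1 row or column, and 16 of these cells held under 100000 fragments. Over 50% of small clusters each lay in 1 row or column in 13 of 16 alternatives that gave any (all of them in 4). In the other alternatives 2 of 5 did so with rescaled FPKM, 0 of 1 with Leiden clustering, and 2 of 6 with values under 1% of the highest in the row or column set to 0. These counts set no least size, so a cluster of 1 cell would always count, and the rate for random small clusters was not computed. Fragments from other wells of the same row or column are a candidate explanation, since genes held by 1 well were found at least 14.3 times as often there as elsewhere, and such transfer would bring 5160 to 15724 fragments into each of the 36 shallower wells by median shares over pairs above 0, or 2932 to 7983 with pairs at 0 included, amounts that 31 and 18 of these wells did not exceed. Low depth cannot be told apart from it, since the planned clustering repeated on the 67 deeper cells alone, with 0 clusters of 10 cells or fewer, leaves out 16 of the 19 cells. Of the 36 shallower wells, 3 held over 2 times the transfer computed from median shares over pairs above 0. No biological explanation was tested, and whether the shallower wells held a cell stays open.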

How the results depend on the processing

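Settings that use fragments, the 1% filter, shares at 100 FPKM or the 67 deeper cells were chosen after the data were seen; the others were planned. No paired analysis was possible because the labels give 1 group and no test was run. Of list medians, 45 of 56 between clusters 1 and 2 and 23 of 32 between basal-like and endothelial-like cells stayed within 1 SD of random lists, and only that of the mesenchymal list changed sign. The 8 endothelial-like cells stayed in 1 cluster in all 5 alternatives, but not apart from the high mitochondrial cells, of which that cluster also held 9 with a pseudocount of 10, 4 of the 4 present with at least 1000000 fragments, 2 with the other gene set and without row I, and 0 with 7 clusters. Depth limits what values under 100 FPKM can show, and in wells under 100000 fragments it limits higher values too. Tox2, found mainly in well H10, stood at 182 FPKM in well H12, which had 14270 fragments. Shares at 100 FPKM in clusters 1 and 2 include 1 and 9 cells of such depth. The cause was not tested for the values below.

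Requiring 2000 genes kept 59.2% of cells. The share of cluster 1 became 26.9% with a pseudocount of 0.1, 29.03% without the gene filter, 27.96% with rescaled FPKM and with the other gene set, 25.8% with Leiden clustering, and 55.2% in the deeper cells. That of cluster 2 became 24.7% with a pseudocount of 0.1, 25.8% with 5 components, 26.9% in the deeper cells and 20.4% with the 1% filter. With 2000 variable genes the best match of both was 1 cluster of 66.7%. List medians for cluster 2 minus 1 became -0.69 (mesenchymal) with a pseudocount of 0.1, -1.91 (endothelial) with 10, and 3.10 (basal) and -0.16 (class I) without each gene's highest cell. With all cells they were 2.64 (contractile), 2.26 (shared luminal) and 0.16 (mesenchymal), and with members of at least 1 FPKM -0.79 (mesenchymal). The endothelial median was -4.41 in the deeper cells and -4.75 with the 1% filter, which gave -1.22 for class I genes, 9 basal members higher and 4 endothelial members lower.

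At 10 FPKM the shares were 27.96% (Krt5), 93.5% (Krt14), 37.6% (Krt8), 44.1% (Krt18), 49.5% (Epcam) and 0% (Top2a). Above 0 they were 56.99% (Krt5), 62.4% (Krt8), 80.6% (Krt18), 86.02% (Epcam) and 8.60% (Mki67). In the deeper cells Krt14 stood at 100%, and at 100 FPKM at 64.2%, with 11.9% (Krt5), 13.4% (Krt8), 23.9% (Krt18), 16.4% (Epcam), 0% (Mki67) and 0% (Top2a). With the 1% filter they were 20.4% (Krt5), 40.9% (Krt14), 26.9% (Krt8), 21.5% (Krt18) and 29.03% (Epcam). Basal and luminal keratins together stood at 78.5% at 1 FPKM, 35.5% at 100 FPKM, 28.4% at 100 FPKM in the deeper cells and 31.2% with the 1% filter. The 35.5% (33 of 93) includes wells under 100000 fragments, where few fragments can give 100 FPKM.

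In the deeper cells, the number of clusters by silhouette width left 23.9% in the largest basal-like cluster. With at least 1000000 fragments the largest basal-like cluster held 43.1% and the cluster of endothelial-like and high mitochondrial cells together 23.5%. A pseudocount of 10 gave 13.4% for the unnamed cluster and 25.4% for that with the endothelial-like cells, and list medians of 4.33 (basal), 3.24 (contractile), 2.21 (keratins), 1.40 (shared luminal), 1.30 (stem cell associated) and 1.31 (Wnt). Without each gene's highest cell they were 2.59 (shared luminal), 4.61 (stem cell associated) and -0.93 (class I). Members higher in basal-like cells numbered 5 (keratins) and 2 (Wnt) with shares at 100 FPKM, and 11 (basal), 12 (contractile) and 5 (keratins) with the 1% filter.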

Other observations

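The tests in this part were chosen after the results were seen, other than a planned one of ribosomal gene detection, and the genes Cd36, Ly6c1, Igfbp5 and Tm4sf1 were picked after their values were seen. Cd36, a fatty acid transporter held out of the clustering (ENSMUSG00000002944, chromosome 5, 17781690 to 17888801, minus strand), averaged 8005 FPKM ± 4826 (SD, n = 8 cells) in the endothelial-like cells, with 8 of 8 cells at 100 FPKM or more, against 257 ± 866 (n = 40) in the basal-like cells, of which 151 remained without the highest. Ly6c1 averaged 3413 ± 3578 and 272 ± 936, the latter 150 without its highest cell. Plin2, a lipid droplet coat protein in the milk protein list, averaged 2098 ± 3062 (1267 without the highest cell) and 3.95 ± 15.4, of which 1.58 remained without the highest. Col4a1, a collagen of basement membranes, averaged 170 ± 194 against 15.2 ± 31.7. In the basal-like cells Igfbp5, a binding protein of insulin-like growth factors, averaged 347 ± 364 and Tm4sf1 1298 ± 1583, against 1.77 ± 1.02 and 264 ± 519, the last 93.8 without its highest cell.

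Of 11 innate defence genes, 3 (Ltf, Cd14 and Lyz2) were listed at 0 in all cells and 4 were at 100 FPKM or more in at least 20% of the deeper cells, as were 6 of 14 immediate-early and stress genes. Slpi, a protease inhibitor of secretions, averaged 6318.5 FPKM ± 8397 in basal-like, 1484 ± 3196 in unnamed and 164 ± 160 in endothelial-like cells, and Cxcl1, a neutrophil chemokine, 2351 ± 4176, 606 ± 1058 and 1043 ± 1675, the last 515 without its highest cell. Sparc, a matrix protein, averaged 927 ± 1405 in basal-like and 930 ± 1732 in endothelial-like cells, the latter 330 without the highest cell. Ier3 averaged 796 ± 1082, 842 ± 2005 and 742 ± 1804, the last 106 and the one before it 421 without the highest cell. Of 33 ribosomal protein genes held out of the clustering, 32 had a lower mean in endothelial-like than in basal-like cells, 22 of them by at least 2-fold, with a median log2 difference of -2.00 (-1.90 and again 32 after rescaling without mitochondrial genes). They took a median of 6.54% of FPKM in basal-like, 3.01% in endothelial-like and 1.14% in unnamed cells. Numbers of these genes above 0 were near complete (32.5 of 33 in basal-like and 31.9 in endothelial-like cells), so a planned test of detection was void. The ribosomal difference was not set against matched random lists. For basal-like minus endothelial-like, the basement membrane and adhesion list had a median of 1.35 at percentile 15.6, and housekeeping 0.70 at 39.3. Matched random lists thus lay lower in the endothelial-like cells as well, and how far the ribosomal genes exceed that shift is not known. Krt14 and Gpihbp1 both reached 100 FPKM in 2 basal-like cells, 1 unnamed cell and 0 endothelial-like cells.

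Endothelial genes in 8 cells of an epithelial sort were weighed against 2 technical explanations. The 8 cells lay in 4 plate rows and 5 plate columns, and each shared a row or column with another of them. Fragments from other wells are argued against in 7 of the 8 cells, whose fragment weight over the endothelial list was over 2 times that computed from their row and column at the 95th percentile of the transfer shares, and stay open in the other, at 1.40 times. For a basal cell in the same capture site, Krt14 was at 100 FPKM or more in 0 of the 8 cells, where 37 of 40 basal-like cells reached it. None of the 8 wells thus reached that level as a whole. FPKM is relative to the whole well, so RNA of a second cell would lower Krt14, and a basal cell with less Krt14 is not excluded. The level of 100 FPKM was also chosen after the data were seen. The count cannot weigh mixed captures in general, since the clustering that set the 8 apart would tend to place those with the basal-like cells. Krt14 of the 8 cells, at 2.15 to 41.6 FPKM with a median of 12.3, may come from other wells, for which the median shares over pairs above 0 give a median of 15.2. The 7 cells may be endothelial cells that passed the sort. That hypothesis came from these same cells, and no biological explanation was tested.

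Basal genes were lower in the 19 cells of the unnamed cluster, by a median log2 difference of 4.69 from the basal-like cells, with 4 of 11 by the size rule. The housekeeping median was 1.81 in the same direction (percentile 66.2). The mitochondrial share of these 19 cells was high in the median but ranged down to 13.8%. The share of FPKM taken by genes annotated as mitochondrial is argued against as the whole cause, since the basal difference was 4.53 after rescaling without these genes. Nuclear copies that hold mitochondrial reads, such as Gm28437, stayed in the rescaled sum, so the part they took was not tested. Lower depth is argued against only in the 4 cells of the cluster with over 1000000 fragments, where the basal difference was 4.48, and stays open in the other 15. Of these 4 cells 2 held an endothelial marker at 100 FPKM or more, and all 4 joined the endothelial-like cells when cells of that depth were clustered alone, so they may differ from the others. The mitochondrial shares of these 4 cells were 14.7%, 17.4%, 33.5% and 58.6%. Loss of cytoplasmic RNA from damaged cells was not tested and stays open, and no biological explanation was tested.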
